A study of Homo sapiens with 3 samples.

How the data were processed

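Total RNA was taken from KMS11 cells, an established human myeloma line, 48 h after the start of lentiviral infection, and biotin-labelled RNA was hybridised to Affymetrix expression arrays, per the labels. There were 3 arrays: 1 for the luciferase control hairpin, 1 for shMMSET#2 and 1 for shMMSET#4, grouped by their source labels. The deposited values are MAS5 intensities, that is, linear signals per probe set, with MAS5 named in the submitters' processing notes and GeneSpring in the series' design text. The versions of these tools and the background and summary settings were not given in the sources used here. The design text names the HG-U133 A array, whereas the value table holds 54675 probe sets whose identifiers are those of the larger HG-U133 Plus 2.0 array, and the probe sets were named on that basis. The 2% trimmed mean was 500.1 on each of the 3 arrays, so the authors' values were already scaled to a common level, and the lowest value on each array was 1, the value of 204 probe sets on the shLuc array, 404 on the shMMSET#2 array and 472 on the shMMSET#4 array. MAS5 scaling to a common trimmed mean assumes that the bulk of the signal is alike, and signals near the floor are noisy, which affects ratios of dim genes most.

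Probe sets were named through the platform annotation, and symbols were brought up to date by Entrez identifier against the RefSeq gene table of GRCh38.p14 for 41043 probe sets. Leaving out 62 control probe sets, 41091 had 1 gene symbol, 1801 had several and were given no name, and 11721 were unnamed here. No coordinates are printed, since the values carry no genome build. Because the trimmed means differed by less than 5%, no rescaling was done. Signals were floored at the 40th percentile of all signals pooled over arrays, 41.2, and log2-transformed. At or under the floor were 36.2% of probe sets on the shLuc array, 41.2% on the shMMSET#2 array and 42.6% on the shMMSET#4 array. Each gene was represented by its probe set with the highest mean signal. Of 19775 genes, 13296 were tested, namely those above the array's median signal on at least 1 array. A ratio with 1 side at the floor is a bound and is written as "at least". Replicates were absent, so genes were called by size with a threshold of 2-fold, and p-values were computed in the limma alternative alone. The precision is limited by the number of arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

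The agreement of the hairpins was set beside 100 simulations of unchanged arrays that share 1 control, with noise per signal decile taken from the difference between the hairpin arrays, which bounds the noise of the hairpin arrays from above because real differences between hairpins add to it. The shLuc array was assumed to have the same noise. All simulated arrays had the same mean signal per gene, and the filter on dim genes was not applied to them again. For each of 27 gene lists, the median log2 ratio was placed among 10000 random lists of the same size matched on deciles of mean signal, as a description of these arrays. List members were counted as lower or higher where both hairpins were at least 1.5-fold from shLuc in the same direction. There were 39 genes in more than 1 list.

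The genes to be named were set by a rule: NSD2 (MMSET), the 12 lowest and 12 highest genes by the smaller of the 2 log2 ratios of like sign (placeholder names skipped), every plasma cell transcription factor on the list, up to 4 members of every other list by the smaller ratio, taken on the side of the list's median, and the 5 highest and 5 lowest genes by the ratio of shMMSET#4 to shMMSET#2. This named 161 genes. The side of the list's median is a reading of the rule made after the data could be seen, and it left out members past 1.5-fold on the other side. Those are named in addition, as are a few others, and the text says that they were chosen after their values were seen. Probe sets of 13 of the 161 disagreed in sign at 1.5-fold. The design, the lists, this rule and the alternatives were fixed before the data were examined. The alternatives were scaling to the same median signal, quantile normalization, no floor, a floor at the 60th percentile, no filter on dim probe sets, a filter at the 75th percentile, a filter on the mean signal, the mean over all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, and limma 3.58.1 in R 4.3.3 with the hairpins taken as 2 samples against the shLuc array, with Benjamini-Hochberg adjustment.

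The steps were tested on simulated data with 13296 tested genes and noise of SD 0.2 on the log2 scale, in the comparison of both hairpins with shLuc. The 200 changed genes were drawn only from genes well above the floor, so recovery among dim genes was not tested. Of genes set 4-fold lower, 100% were called at least 2-fold lower with both hairpins, and of genes set 4-fold higher, 100% were called higher. Of genes set exactly 2-fold lower, 38.8% were called, because the threshold lies at that size, and 4 unchanged genes were called. This noise is below that taken from the hairpin arrays, 0.28 to 0.56 by signal decile, with which unchanged arrays gave on average 175 genes lower and 149 higher with both hairpins.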

Results

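The study profiled messenger RNA in KMS11, a human multiple myeloma cell line that carries the t(4;14) translocation. This translocation places MMSET (current symbol NSD2), a histone methyltransferase gene, under immunoglobulin enhancers and raises its expression. The cells were infected with lentiviruses that carried short hairpin RNAs, which silence a transcript by RNA interference, and were collected at 48 h. There were 3 groups with 1 array each. The control hairpin was directed at luciferase, a gene that human cells lack, and is called shLuc. The other groups received either of a pair of hairpins against MMSET, shMMSET#2 and shMMSET#4. According to the series title, the comparison asks which transcription factors needed for the survival of such myeloma cells depend on MMSET. Because no group had a replicate, differences are described by size rather than by a p-value, and "lower" and "higher" describe these 3 arrays. The number of arrays limits the precision. The only measure of spread is the difference between the hairpin arrays, which also holds real differences between the hairpins. Over the 13296 tested genes these arrays lay within 1.28-fold of each other for the median gene and within 2.37-fold for 95% of genes, and within 1.95-fold for 95% of the brightest 3 deciles of genes. The median probe set signal was 77.4 on the shLuc array, 62.0 on the shMMSET#2 array and 59.5 on the shMMSET#4 array. The log2 signal of the 3' control probe set of ACTB exceeded that of the 5' probe set by 1.70 on the shLuc array, 1.14 on the shMMSET#2 array and 1.14 on the shMMSET#4 array. For GAPDH the same difference was 0.04, 0.10 and 0.00.

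In the deposited scaling the targeted gene was lower with both hairpins, and more so with shMMSET#2. All 6 NSD2 probe sets were lower with shMMSET#2 than with shLuc, with log2 ratios from -2.69 to -0.54 and a median of -1.33 (SD 0.99 over the 6 probe sets). With shMMSET#4, 5 of the 6 were lower, with log2 ratios from -1.62 to 0.05 and a median of -0.48 (SD 0.59). On the brightest probe set the signal was 10300 with shLuc, 7032 with shMMSET#2 and 7476 with shMMSET#4, which is 1.46-fold and 1.38-fold lower than shLuc. In the brightest signal decile, which holds this probe set, the hairpin arrays lay within 1.79-fold of each other for 95% of genes. Both folds are inside that spread. Scaling to the same median signal raised the median log2 ratio of all tested genes from -0.04 to 0.26 with shMMSET#2 and from -0.02 to 0.34 with shMMSET#4. It raises NSD2 ratios alike, so the size of the NSD2 difference depends on the scaling. With shMMSET#4 most of the log2 ratio of -0.46 on the brightest probe set would be lost. A probe set at -0.13 with shMMSET#4 would turn positive, so a lower NSD2 level with this hairpin is itself not secure against the scaling. The probe set with the largest difference with shMMSET#4 was 5.45-fold lower with shMMSET#2 and 3.07-fold lower with shMMSET#4. The signal was lower with shMMSET#2 than with shMMSET#4 on all 6 probe sets.

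**Figure D1:**
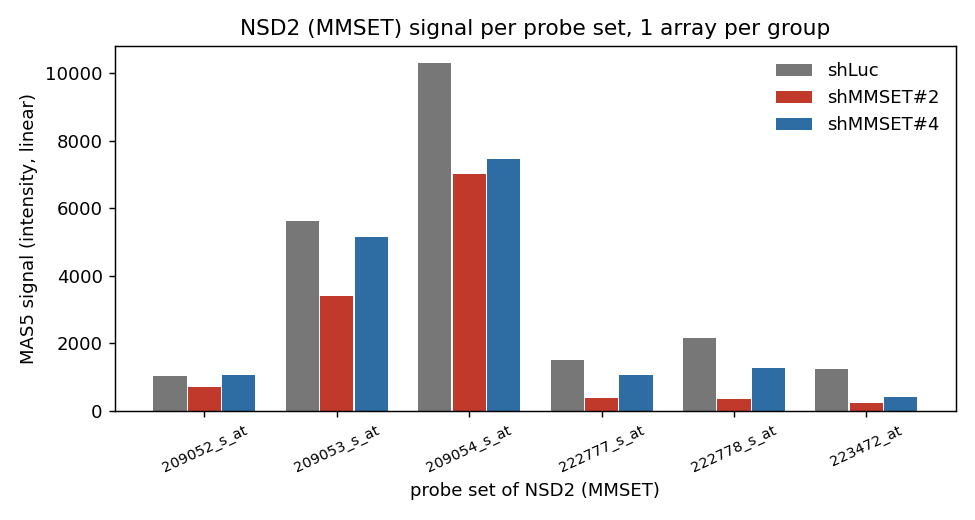
Signal (linear intensity, vertical axis) of the 6 NSD2 probe sets (horizontal axis) on the shLuc, shMMSET#2 and shMMSET#4 arrays, with 1 bar per array and no error bars because each group has 1 array. All 6 bars for shMMSET#2 are below those for shLuc, and 5 of the 6 bars for shMMSET#4 are.

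With shMMSET#2, several regulators on the list of plasma cell transcription factors had lower signals than with shLuc. MYC was 3.23-fold lower (signal 9616 with shLuc and 2979 with shMMSET#2), MAF was 2.92-fold lower, and IRF4, on which myeloma cells depend for survival, was 2.86-fold lower (5291 and 1853). POU2AF1, a coactivator of B-lineage genes, was 2.37-fold lower, PRDM1, the repressor that sets up plasma cell differentiation, was 2.29-fold lower, and XBP1, a regulator of the secretory apparatus, was 1.88-fold lower. Of 23 tested plasma cell identity and surface genes, 9 were at least 1.5-fold lower with shMMSET#2 and 2 were at least 1.5-fold higher. The lowest were HGF (17.0-fold, hepatocyte growth factor), IL6R (11.7-fold, the interleukin 6 receptor) and SLAMF7 (5.85-fold). FCRL5, an Fc receptor-like gene, was 2.70-fold lower with shMMSET#2 and 1.80-fold lower with shMMSET#4. The probe sets of HGF were all lower with shMMSET#2 but disagreed in sign with shMMSET#4. In all, 1417 tested genes were at least 2-fold lower with shMMSET#2 and 757 were at least 2-fold higher. Unchanged arrays simulated with the spread seen between the hairpin arrays gave on average 611 genes past 2-fold in each direction. With every array scaled to the same median signal, the counts became 723 lower and 1627 higher.

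With shMMSET#4, these regulators were within 1.31-fold of shLuc on their brightest probe sets. MYC was 1.27-fold lower, IRF4 1.31-fold lower, MAF 1.08-fold lower, POU2AF1 1.27-fold lower and XBP1 1.14-fold lower, while PRDM1 was 1.14-fold higher on its brightest probe set and 1.44-fold and 1.42-fold lower on its other 2. A dimmer IRF4 probe set was 2.13-fold lower, and the 5 other MAF probe sets were 1.03-fold to 1.47-fold lower. Other transcription factor genes were lower with this hairpin: KLF2 was 2.55-fold lower on its brightest probe set and 1.12-fold higher on a dimmer one, and MEF2C, a MADS box factor of B cells, was 3.85-fold lower (1500 with shLuc and 389 with shMMSET#4). IL6R was 3.23-fold lower and SLAMF7 was 1.51-fold lower on its brightest probe set, with log2 ratios of -0.37 and 0.05 on its other 2. In all, 1190 tested genes were at least 2-fold lower with shMMSET#4 and 896 were at least 2-fold higher, against simulated averages of 609 and 606. With every array scaled to the same median signal, the counts became 501 lower and 1980 higher.

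Both hairpins together gave 579 genes at least 2-fold lower and 376 at least 2-fold higher than shLuc. Among named genes with the lowest shared ratios were SEMA3C, a secreted semaphorin (11.6-fold lower with shMMSET#2 and 9.52-fold lower with shMMSET#4), DCC, a netrin receptor (16.0-fold and 7.28-fold), ITGA8, an integrin subunit (7.24-fold and 6.62-fold), and OTOGL (6.91-fold and 5.36-fold). LINC01088 was at least 17.0-fold lower with each hairpin, CREB5 at least 8.52-fold lower with each, and ANXA1, a phospholipid-binding protein gene, 6.53-fold lower with shMMSET#2 and at least 15.6-fold lower with shMMSET#4, because their signals reached the floor of 41.2. SLC15A2, GRB14, ZC2HC1B, MACROD2 and SAMSN1 complete the 12 lowest, each with at least 1 hairpin at the floor. The 12 highest included WSB2, a substrate receptor of a ubiquitin ligase (10.5-fold higher with shMMSET#2 and 8.58-fold higher with shMMSET#4), GPS1, a subunit of the COP9 signalosome (signal 52.4 with shLuc, 468 with shMMSET#2 and 575 with shMMSET#4), BRWD1 (8.19-fold and 5.88-fold on its brightest probe set, with log2 ratios from -0.55 to 0.33 with shMMSET#4 on 6 others), NLRP7 (5.97-fold and 7.95-fold), PRKAR2B, a regulatory subunit of protein kinase A (5.96-fold and 9.64-fold), UBE2V2, a ubiquitin-conjugating enzyme variant (5.75-fold and 5.22-fold), and EIF5A2 (5.59-fold and 5.82-fold). KLHL5 was 5.62-fold and 8.83-fold higher, although its probe sets disagreed in sign. SLC27A5, FAXDC2, NUDT14 and CPEB1 were at the floor with shLuc. Of the 579 lower genes, 300 had at least 1 hairpin at the floor, and of the 376 higher genes, 65 had shLuc at the floor, so that their ratios are bounds.

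Part of this agreement arises because both ratios use the same shLuc array. Across the tested genes, which are not independent replicates, the log2 ratios of the hairpins had a Pearson correlation of 0.64 and a Spearman correlation of 0.62, against averages of 0.50 and 0.48 in 100 simulations of unchanged arrays that share 1 control. The covariance was 0.34 against a simulated 0.17, and 72.9% of genes had the same sign against a simulated 67.0%. The simulations gave on average 175 genes lower and 149 genes higher with both hairpins, and independent lists of the observed sizes would share 127 and 51.0 genes. With 1 control array the control could not be split, and the simulations assumed that its noise equals that of the hairpin arrays. A noisier shLuc array would raise the simulated values, so part or all of the excess may come from the shared control. Scaling to the same median signal turned the balance from 60.6% lower among genes past 2-fold with both hairpins to 19.8% (229 lower and 926 higher), and quantile normalization to 40.1% (339 lower and 507 higher). Without rescaling it was 51.1% with no floor, 45.3% with a floor at the 60th percentile, 37.7% with a filter at the 75th percentile and 47.8% with a filter on the mean signal. It was 60.6% with no filter, 60.3% with the mean over all probe sets and 66.2% without probe sets ending in _x_at or _s_at.

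**Figure D2:**
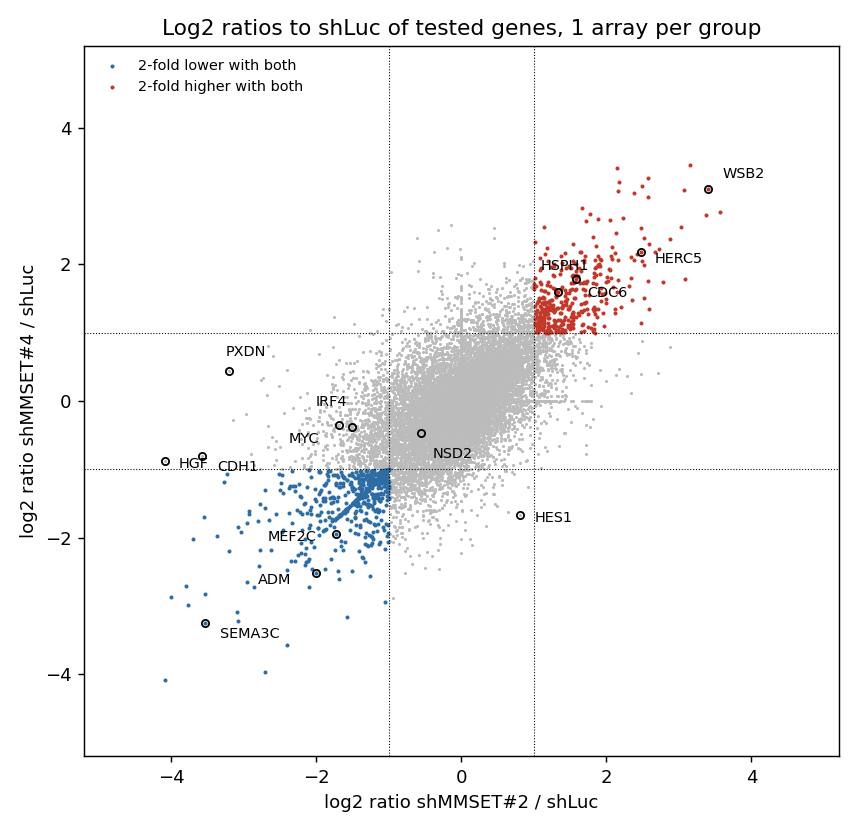
Log2 ratio to shLuc with shMMSET#2 (horizontal axis) and shMMSET#4 (vertical axis) for the 13296 tested genes, 1 point per gene, with dotted lines at 2-fold. The 579 genes 2-fold lower with both hairpins are blue and the 376 genes 2-fold higher are red, circles mark genes named in the text, and 1 gene lies outside the axes. MYC and IRF4 lie far left of 0 but near 0 on the vertical axis, and points on straight lines had a signal set to the floor.

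The list of plasma cell transcription factors fixed beforehand also holds factors of other B-lineage stages, such as BCL6. Of its 36 members, 34 were tested, and 9 of them were at least 1.5-fold lower with both hairpins, 3 were higher with both and 22 were neither. The 9 were MEF2C (3.32-fold with shMMSET#2 and 3.85-fold with shMMSET#4), CREB3L2, a factor of the secretory pathway (3.01-fold and 2.81-fold), BCL6, the germinal centre repressor (2.97-fold and 2.51-fold), BACH2 (3.15-fold and 1.53-fold), FLI1 (1.92-fold and 1.71-fold), the NF-kB subunit gene REL (1.69-fold and 1.61-fold), KLF6 (1.65-fold and 1.83-fold), MEF2D (1.65-fold and 2.01-fold) and ETV6 (1.60-fold and 1.51-fold). RUNX3 (1.68-fold and 1.69-fold), E2F1 (1.74-fold and 1.63-fold) and ATF6 (1.84-fold and 1.65-fold) were higher with both. With shMMSET#2, 17 members were at least 1.5-fold lower and 4 were higher, and with shMMSET#4, 15 were lower and 3 were higher. IKZF1 and IKZF3, which encode Ikaros and Aiolos, were within 1.42-fold of shLuc with both hairpins on their brightest probe sets, as were NFKB1, RELB, TCF4, BATF and PAX5. Dimmer IKZF1 probe sets were up to 1.78-fold higher with shMMSET#2 and up to 1.72-fold higher with shMMSET#4. STAT3 was 1.32-fold and 1.61-fold lower. SPIB was 2.49-fold higher with shMMSET#2 and 1.34-fold higher with shMMSET#4, and EBF1 was 1.49-fold and 2.44-fold lower. A dimmer SPIB probe set was 1.67-fold higher and 1.42-fold lower. With shLuc at the floor, a dimmer EBF1 probe set was at least 1.58-fold and at least 1.03-fold higher. ZNF215 was 3.78-fold lower with shMMSET#2 and 1.27-fold lower with shMMSET#4. TCF3 was 2.18-fold and 1.12-fold lower. Probe sets of FLI1, ETV6, TCF3, BHLHE41, ZBTB20 and NFKB2 disagreed in sign at 1.5-fold. The last 3 were 1.33-fold, 1.22-fold and 1.03-fold lower with shMMSET#2 and 3.08-fold, 2.72-fold and 1.62-fold lower with shMMSET#4 on their brightest probe sets.

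The median log2 ratio of the list was -0.63 with shMMSET#2, below all of 10000 random lists matched on signal, and -0.35 with shMMSET#4, at percentile 0.09. With the mean over all probe sets of each gene the median with shMMSET#2 was -0.20, at percentile 3.53. Scaling to the same median signal moved the median with shMMSET#4 to 0.03, at percentile 0.1, so that its sign depends on the scaling. The percentile could hardly change, because this scaling shifts the log2 ratios of all genes alike, apart from effects of the floor and of the probe set chosen.

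**Figure D3:**
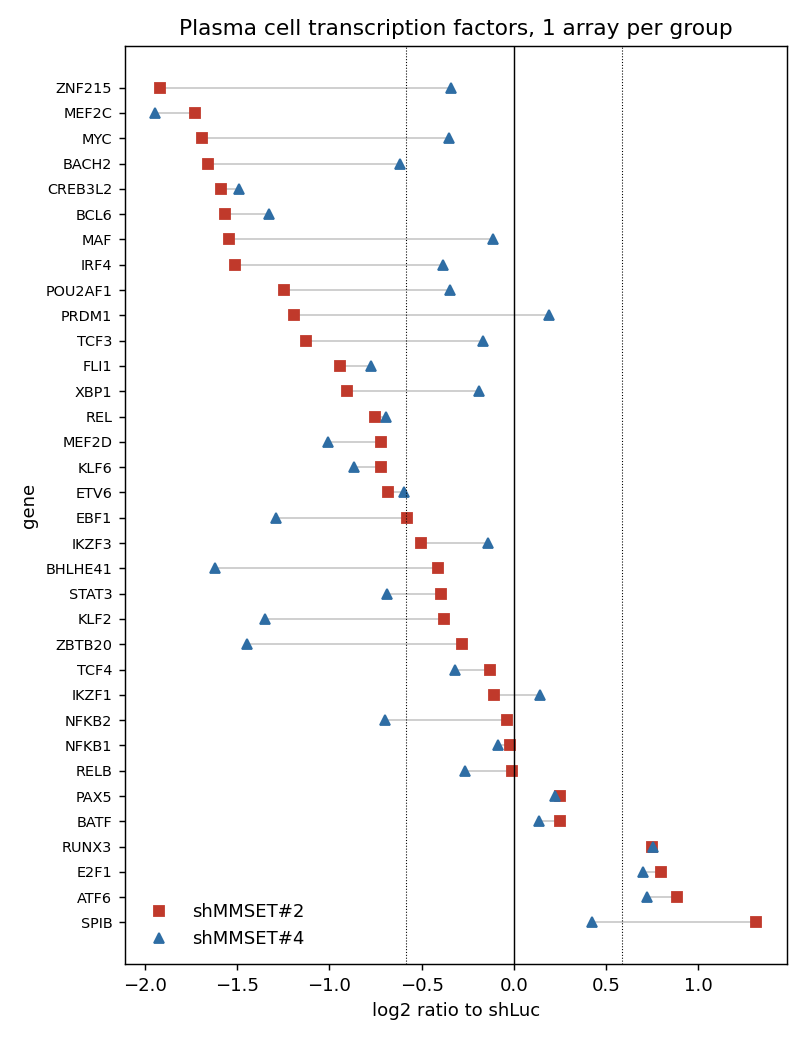
Log2 ratio to shLuc (horizontal axis) of the 34 tested plasma cell transcription factor genes (vertical axis), with squares for shMMSET#2 and triangles for shMMSET#4, 1 array each and no error bars. Dotted lines mark 1.5-fold. MYC, MAF, IRF4 and PRDM1 have squares at -1.19 or lower and triangles between -0.38 and 0.19, while MEF2C, CREB3L2 and BCL6 have both symbols at -1.33 or lower.

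Among genes of DNA replication, a part was higher with both hairpins. Of 38 tested members of the G1/S and replication list, 17 were at least 1.5-fold higher with both, none was lower with both and 21 were neither. UNG, the uracil-DNA glycosylase, was 4.49-fold higher with shMMSET#2 and 8.43-fold higher with shMMSET#4, CDC6, which loads the replicative helicase, had signals of 632 with shLuc, 1894 with shMMSET#2 and 2180 with shMMSET#4, and the helicase subunit genes MCM5 (2.89-fold and 3.12-fold) and MCM2 (2.87-fold and 2.70-fold) were higher too. The list medians of 0.64 and 0.88 lay above all 10000 matched random lists. Of 46 tested G2/M and mitosis genes, 43 were neither lower nor higher with both hairpins, with medians of -0.07 (percentile 16.9) and -0.16 (percentile 1.2), which scaling to the same median signal turned to 0.25 and 0.22. CENPE was 1.61-fold and 2.02-fold lower and KIF2C 1.71-fold and 1.87-fold lower, whereas TOP2A and CCNB2 were within 1.55-fold. The 1 member higher with both, chosen after its values were seen, was MAD2L1 (2.28-fold and 2.61-fold). Of 39 MYC target genes, 6 were higher with both and none was lower with both, among them CDK4 (2.43-fold and 2.14-fold), EXOSC5 (1.90-fold and 2.27-fold), and MCM4 and MCM5, which are on the replication list too. Their median was 0.10 with shMMSET#2 (percentile 75.5) and 0.43 with shMMSET#4 (above all matched lists).

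Among interferon response genes, a part was higher with both hairpins. Of 34 tested members, 15 were at least 1.5-fold higher with both and 1, GBP1, was lower (1.98-fold and 3.87-fold, chosen after its values were seen), while 18 were neither. HERC5, a ligase for the ubiquitin-like modifier ISG15, was 5.54-fold higher with shMMSET#2 and 4.55-fold higher with shMMSET#4. IFIT3 was 5.07-fold and 3.49-fold higher, IFI35 4.23-fold and 4.80-fold, and DDX60 8.45-fold and 3.46-fold. The list medians of 0.83 and 0.61 were above all matched random lists. Among the B cell markers, HLA-DRA was 2.12-fold and 2.29-fold higher, HLA-DPB1 2.82-fold and 2.63-fold, and HLA-DPA1 2.19-fold and 2.89-fold. LY86 was 2.24-fold and 2.48-fold higher. Of members chosen after their values were seen, HLA-DRB1 was 2.08-fold and 1.66-fold higher, CD74 1.28-fold and 1.25-fold higher, CIITA 1.03-fold higher with shMMSET#2 and 2.01-fold lower with shMMSET#4, and VPREB3 at least 1.32 lower on the log2 scale and 1.83-fold lower. Of 18 tested B cell markers, 5 were higher with both, 1 was lower and 12 were neither, with medians of 0.20 and 0.27 at percentiles 96.6 and 96.6. Without probe sets ending in _x_at or _s_at the median with shMMSET#4 turned to -0.12.

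Of 16 tested heat shock genes, 10 were at least 1.5-fold higher with both hairpins, none was lower with both and 6 were neither, with medians of 0.83 and 0.82 above all matched lists. HSPH1 was 2.53-fold higher with shMMSET#2 and 3.03-fold higher with shMMSET#4, HSP90AA1 2.17-fold and 2.23-fold, and CHORDC1 2.14-fold and 2.25-fold. The log2 ratios of FKBP4 were 1.11 and 1.32. Of 28 proteasome subunit genes, 6 were higher with both, none was lower with both and 22 were neither, with PSMB5, the subunit that bortezomib inhibits, 2.90-fold and 2.44-fold higher, PSMC3 2.45-fold and 2.15-fold, PSMB6 2.28-fold and 2.00-fold, and PSMC6 1.83-fold and 1.91-fold. Their medians were 0.37 (percentile 99.9) and 0.29 (percentile 99.3).

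Of 37 tested cytosolic ribosomal protein genes, 9 were at least 1.5-fold lower with both, 1 was higher and 27 were neither. The higher member, chosen after its values were seen, was RPS21 (1.58-fold and 1.53-fold). RPL12 had signals of 34214 with shLuc, 17494 with shMMSET#2 and 21417 with shMMSET#4. RPL32 was 1.75-fold and 1.59-fold lower, RPS9 1.66-fold and 1.63-fold, and RPL6 1.65-fold and 1.56-fold. The medians of -0.58 and -0.57 were below all matched random lists. The brightest decile used for matching starts at a mean signal of 4797, and 99% of probe sets on the shLuc array read 15325 or less. RPL12, RPL32, RPS9 and RPL6 read at least 34214 there, so their matched genes were mostly dimmer. After quantile normalization they were -0.11 and -0.09, at percentiles 3.35 and 6.67, inside the central 95% of matched lists.

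Of 29 tested genes of hypoxia and glycolysis, 9 were at least 1.5-fold lower with both hairpins, 2 were higher and 18 were neither. The higher members, chosen after their values were seen, were EGLN1 (2.60-fold and 2.74-fold) and ENO2 (2.17-fold and 2.08-fold). ADM, the gene of adrenomedullin, was 4.01-fold and 5.71-fold lower, PFKFB4 8.48-fold and 3.61-fold, PDK1, a kinase that inhibits pyruvate dehydrogenase, 5.65-fold and 2.47-fold, and NDRG1 6.85-fold and 1.99-fold. The median was -0.72 with shMMSET#2, below all matched random lists, and -0.19 with shMMSET#4, at percentile 2.65, which quantile normalization turned to 0.01 at percentile 42.7 and scaling to the same median signal to 0.19. Of 22 tested NF-kB target genes, 7 were lower with both hairpins and 1 was higher, among them CXCL10 (2.54-fold and 3.36-fold), ICAM1 (2.14-fold and 1.63-fold), MAP3K8 (2.29-fold and 1.84-fold) and TNFAIP3, a feedback inhibitor of the pathway (1.95-fold and 1.83-fold). The higher member was NFKBIE (1.88-fold and 1.54-fold, chosen after its values were seen). Their medians were -0.09 (percentile 37.6) and -0.35 (percentile 1.76), which scaling to the same median signal turned to 0.23 and 0.0339.

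Of 27 lists, 7 lay in the same outer 2.5% of matched random lists with both hairpins: transcription factors, replication, interferon response, heat shock, proteasome, ribosomal protein and DNA double-strand break repair genes. Because both ratios use the same shLuc array and members of a list can vary together, a list shifted on that array falls in the same tail with both hairpins, and the number of such lists without any effect was not estimated. Of 29 tested repair genes, 4 were higher with both and 1 was lower, with MRE11, a nuclease of break repair, 2.92-fold and 3.30-fold higher and medians of 0.28 (percentile 98.0) and 0.32 (percentile 99.4). RAD51C was 1.59-fold and 1.70-fold higher, the kinase gene ATR 1.59-fold and 1.67-fold, and XRCC4 1.63-fold and 1.59-fold, although its probe sets disagreed in sign. The lower member was RAD54B (2.26-fold and 2.58-fold, chosen after its values were seen). Of 106 named genes at least 1.5-fold from shLuc with both hairpins, 59 had another probe set above the median signal. In 17 of these no other probe set reached 1.5-fold with both in the same direction: ATF3, ATF6, BACH2, BRWD1, CPEB1, CREB3L2, E2F1, FLI1, ICAM1, KIF2C, MRE11, RAD51C, RBL1, SAMSN1, SEPTIN9, SLAMF7 and TNFAIP3. For comparison, 11.9% of all tested genes were at least 1.5-fold lower with both hairpins and 8.60% were higher.

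**Figure D4:**
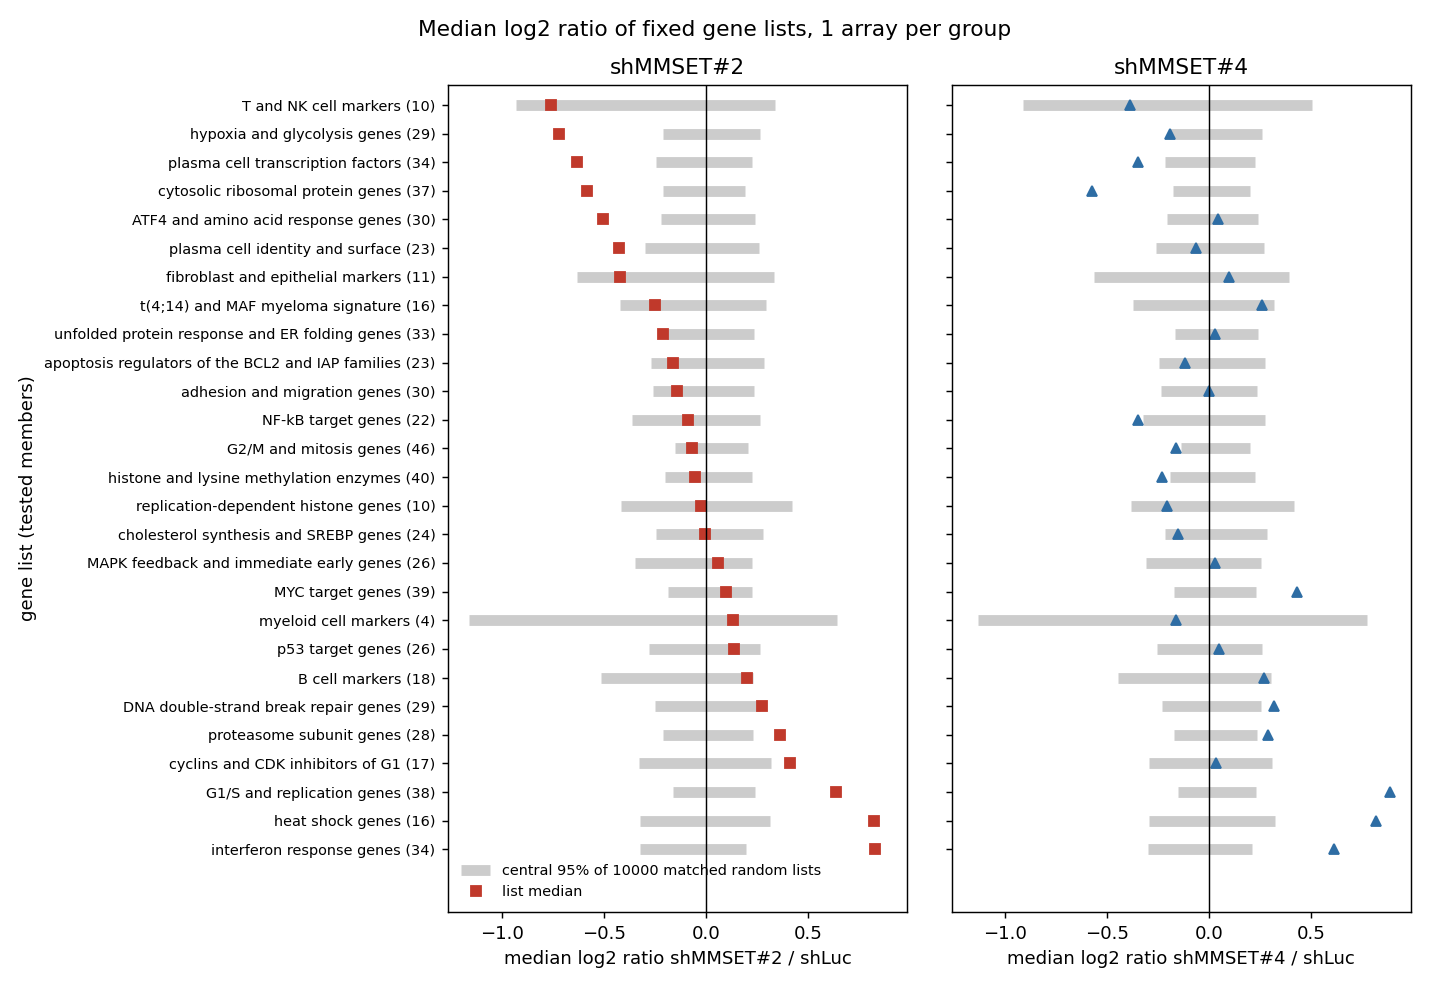
Median log2 ratio to shLuc (horizontal axis) of each of the 27 gene lists (vertical axis, tested members in parentheses) with shMMSET#2 on the left and shMMSET#4 on the right, 1 array each. Grey bars span the central 95% of 10000 random lists matched on signal. The lists of G1/S and replication, heat shock and interferon response genes lie right of the bars with both hairpins, at medians from 0.61 to 0.88, and ribosomal protein genes lie left of them at -0.58 and -0.57.

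The direct comparison of the hairpins does not use the shLuc array. In it, 877 tested genes were at least 2-fold higher with shMMSET#4 than with shMMSET#2 and 494 were at least 2-fold lower. PXDN, a peroxidase of the extracellular matrix, was 12.5-fold higher with shMMSET#4 (signal 3965 and 317 with shMMSET#2), GPM6B was higher by 3.47 on the log2 scale, KIAA1549L 9.55-fold and HGF 9.28-fold. PXDN, GPM6B and KIAA1549L were lower than shLuc with shMMSET#2 and higher than it with shMMSET#4. RAP1A was the most extreme: 2 of its probe sets read 38422 and 34060 with shMMSET#4 and at most 85.3 on the other arrays, while another probe set of the same gene read 2425 with shMMSET#4 and 2116 with shMMSET#2, so its probe sets disagreed. The lowest with shMMSET#4 were CCDC28B (5.64-fold lower than with shMMSET#2), the Notch target HES1 (5.58-fold), LINC01585 (at least 5.14-fold), IFITM1 (4.93-fold) and CEACAM1 (at least 4.83-fold). Plasma cell identity and surface genes, with 23 tested members, differed as a list: their median was -0.43 with shMMSET#2 (percentile 0.33) and -0.07 with shMMSET#4 (percentile 27.5), the latter 0.32 after scaling to the same median signal, and 4 were lower with both, 1 was higher and 18 were neither. The higher member was NCAM1 (1.63-fold and 1.53-fold, chosen after its values were seen), whose probe sets disagreed in sign. The list of ATF4 and amino acid response genes had medians of -0.50 (percentile 0.01) and 0.04 (percentile 60.6) over 30 tested members, of which 2 were lower with both, 2 were higher and 26 were neither. VLDLR was 4.90-fold lower with shMMSET#2 and 2.49-fold lower with shMMSET#4, the stress factor gene ATF3 1.83-fold and 2.47-fold, and CTH 2.23-fold and 1.47-fold. The members higher with both, chosen after their values were seen, were CEBPB (1.84-fold and 2.46-fold) and WARS1 (1.82-fold and 3.09-fold). Unfolded protein response and ER folding genes had medians of -0.21 (percentile 1.6; 0.11 after scaling to the same median signal) and 0.03 (percentile 49.0) over 33 members, of which 1 was lower with both, 3 were higher and 29 were neither. ERN1, the gene of the ER stress sensor IRE1, was 1.97-fold and 1.46-fold lower, and the log2 ratios were -0.59 and -0.48 for DNAJC10 and -0.51 and -0.59 for HERPUD1, none of which reached 1.5-fold with both. The member lower with both was CREB3L2, and those higher were ATF6 and, chosen after their values were seen, CANX (1.94-fold and 2.28-fold) and CRELD2 (2.04-fold and 3.22-fold). For these 3 lists and for hypoxia and glycolysis genes (median 0.44) the median log2 ratio of shMMSET#4 to shMMSET#2 lay above all matched random lists. It was also in the upper 2.5% for MYC target genes (0.28, percentile 99.9), G1/S and replication genes (0.22, percentile 99.8) and the t(4;14) and MAF signature (0.43, percentile 99.6). In the other direction, interferon response genes were lower with shMMSET#4 than with shMMSET#2 (-0.44, below all matched random lists), as were cholesterol synthesis genes (-0.29, percentile 0.13). No replicate was available to test any of these differences.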

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

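The test of the Alu control probe set and the differences per poly-A spike were chosen after their values were seen, and the other tests were not. Named genes at least 1.5-fold below shLuc with one hairpin and at least 1.5-fold above it with the other are listed here, and with 1 array per group none of these differences was tested. The log2 ratio of shMMSET#4 to shMMSET#2 was 3.47 for GPM6B and 3.26 for KIAA1549L, which were lower than shLuc with shMMSET#2. It was -2.50 for CCDC28B, -2.48 for HES1, -2.36 for LINC01585 and -2.27 for CEACAM1, which were lower than shLuc with shMMSET#4. For LINC01585 and CEACAM1 these values are bounds, because the signal with shMMSET#4 was at the floor. Other probe sets above the median signal did not all share these opposite directions: that of KIAA1549L was lower with both hairpins, that of HES1 was higher with both, and 1 each of GPM6B and CEACAM1 was higher with both. No group was large enough for a check of single outlying samples.

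Probe sets without a single gene name were not used in the comparisons, and 92 of the 6069 tested ones were at least 2-fold higher with both hairpins than with shLuc. A larger number, 649 (10.7%), were at least 2-fold lower with both, against 7.06% of named probe sets matched on signal. A higher low-end signal on the shLuc array was tested as an explanation: after quantile normalization 5.54% of unnamed probe sets were lower against 3.30% of matched named ones, a ratio of 1.68, between the values set for and against it (1.2 and 2). More unspliced RNA or genomic DNA in the shLuc sample would lower the Alu control probe set with both hairpins: relative to the hybridisation spikes its log2 ratio was -0.28 with shMMSET#2 and -0.18 with shMMSET#4, so the 2 explanations cannot be told apart and neither is excluded. An effect of MMSET silencing on such transcripts stays open and was not tested.

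The genes past 2-fold with both hairpins, 579 lower and 376 higher, rest on a single shLuc array. Single probe sets that misread that array are argued against for the genes with another bright probe set, 177 of the 579 and 171 of the 376: the other probe sets had a median log2 ratio of -0.94 and 0.59, against -0.10 for 12124 background probe sets. The rest of the genes could not be tested this way. The brightest other probe set was past 1.5-fold with both hairpins in 59.3% of the 177 genes and in 45.6% of the 171. Single misread probe sets therefore stay possible for part of the genes in each direction. Unchanged arrays that share 1 control gave at most 215 lower and 187 higher genes in simulation. The noise of the shLuc array itself was assumed rather than measured, and the noise taken for dim genes may be too low. The simulations also left out the higher low-end signal of the shLuc array and the filter on dim genes. A noisier or otherwise unusual shLuc sample could still have added to both counts. MMSET silencing, which the labels name, stays among the open explanations as untested.

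The median of the ribosomal protein genes was low with both hairpins, with 9 of 37 members lower with both, 1 higher and 27 neither. A signal-dependent difference between the arrays is a candidate explanation, since after quantile normalization the higher of the percentiles of the list median was 6.67, inside the central 95% of matched lists. A weaker labelling of full-length RNA on the shLuc array stays open: the median 3' to 5' log2 difference of the poly-A spikes was 0.16 larger on the shLuc array than on the higher hairpin array, between the values set for and against it (0.3 and 0.1). The median of the differences per spike was 0.34 against shMMSET#2 and 0.29 against shMMSET#4, with the spike phe at -0.03 and 0.04 and the other 3 at 0.27 to 0.55, and the ACTB difference was larger by 0.56 against each. An effect of MMSET silencing was not tested separately.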

How the results depend on the processing

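All alternatives were planned. With 1 array per group, these values show how far the processing moves the counts, not how far another culture would. Per array, 36.2% to 42.6% of probe sets were at or under the floor. No paired analysis was possible because each group has 1 array. Counts that moved by at most 1.5 times are not listed. The cause was not tested unless the setting itself names it, as fewer genes tested or another threshold do.

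Scaling to the same median signal raised the median log2 ratio of all tested genes from -0.04 to 0.26 with shMMSET#2 and from -0.02 to 0.34 with shMMSET#4, and signs of small differences follow it. Genes lower and higher became 723 and 1627 with shMMSET#2, 501 and 1980 with shMMSET#4, and 229 and 926 with both hairpins, and the lower share among the last fell from 60.6% to 19.8%. The correlation of the hairpins was 0.62. Medians of the transcription factors were -0.31 with shMMSET#2 and 0.0312 with shMMSET#4, the latter with a changed sign, as had G2/M and mitosis genes (0.22), NF-kB target genes (0.0339) and histone and lysine methylation enzymes (0.15) with shMMSET#4 and unfolded protein response genes with shMMSET#2 (0.11). Quantile normalization gave 775 lower with shMMSET#4 and 339 lower with both, a lower share of 40.1% and a correlation of 0.63.

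No floor gave 598 genes higher with both and a correlation of 0.59. A floor at the 60th percentile gave 715 genes lower with shMMSET#2, 519 lower with shMMSET#4, 216 lower with both and 732 apart between the hairpins. A filter at the 75th percentile, with fewer genes tested (8195), gave 560 lower and 472 higher with shMMSET#2, 380 lower and 522 higher with shMMSET#4, 152 lower with both, 621 apart between the hairpins and a correlation of 0.65. A filter on the mean signal gave 328 lower with both, and the lower share among genes past 2-fold with both was 47.8%. That share was 45.3% with the floor at the 60th percentile and 37.7% with the filter at the 75th percentile. The mean over all probe sets of a gene gave 864 lower and 471 higher with shMMSET#2, 706 lower and 550 higher with shMMSET#4, 332 lower and 219 higher with both, 792 apart between the hairpins and a transcription factor median of -0.20 with shMMSET#2. Without probe sets ending in _x_at or _s_at, NSD2 was read from another probe set at -2.45 and -1.62, the transcription factor median with shMMSET#2 was -0.45, and the median of cyclins and CDK inhibitors with shMMSET#2 changed sign to -0.0784.

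A threshold of 1.5-fold gave 2997 lower and 2149 higher with shMMSET#2, 2740 and 2294 with shMMSET#4, 1587 and 1144 with both, and 4057 apart between the hairpins. A threshold of 3-fold gave 353 and 174, 260 and 222, 104 and 88, and 280. limma with the hairpins as 2 samples, 1 residual degree of freedom and the shLuc array assumed to vary as the hairpins do called 0 genes lower and 0 higher at an adjusted p under 0.05, with a smallest adjusted p of 0.519, and 750 lower and 518 higher at an unadjusted p under 0.05. The number of lists in the same outer 2.5% with both hairpins was 5 to 9 over the 9 settings that change the values or genes, against 7. Of 482 list medians under these settings, 48 changed sign, 24 of them with a scaling. Of these, 6 had been in an outer 2.5% of matched random lists and are given above. Apart from those 6, 370 moved by less than the SD of matched random lists and 106 by more.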

Other observations

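Genes of apoptosis and feedback signalling held single members with larger differences. Among 23 tested apoptosis regulators, 1 was lower with both hairpins, 1 was higher (BID, 2.18-fold and 1.77-fold, chosen after its values were seen) and 21 were neither, with list medians of -0.16 and -0.12 at percentiles 10.1 and 16.5, which scaling to the same median signal turned to 0.16 and 0.26. BCL2L11, the gene of the cell death mediator BIM, was 2.67-fold lower with shMMSET#2 and 2.12-fold lower with shMMSET#4. MCL1, a survival factor of myeloma cells, was 1.497-fold lower with shMMSET#2 and 1.74-fold lower with shMMSET#4 on its brightest probe set. It did not reach 1.5-fold with both, and its probe sets disagreed in sign. BAK1 was 1.55-fold and 1.31-fold lower, and BMF 1.41-fold and 2.30-fold lower. Of 26 p53 target genes, 3 were higher with both and 1 was lower, with medians of 0.14 and 0.05 (percentiles 83.8 and 64.1), and CDKN1A was 1.67-fold and 1.88-fold higher. TP53I3 was 2.30-fold and 1.67-fold higher, TNFRSF10A, a death receptor gene, 1.73-fold and 1.51-fold, and GADD45B 1.90-fold and 1.47-fold. The lower member was PLK3 (3.10-fold and 4.53-fold, chosen after its values were seen), whose probe sets disagreed in sign. Of 26 MAPK feedback and immediate early genes, 4 were higher and 3 lower with both, with medians of 0.06 and 0.03 (percentiles 78.9 and 66.2). The median with shMMSET#4 was -0.22 with the filter at the 75th percentile and -0.14 with the filter on the mean signal. The feedback inhibitors SPRED1 (5.73-fold and 3.99-fold) and DUSP6 (2.59-fold and 3.78-fold) were higher with both, as was ETV5, at least 4.51-fold and at least 9.22-fold, because shLuc was at the floor. The lower members were KLF6 and, chosen after their values were seen, FOS (2.47-fold and 2.61-fold) and JUN (1.77-fold and 3.83-fold). Cyclins and CDK inhibitors of G1 had medians of 0.41 (percentile 99.5) and 0.03 (percentile 55.3) over 17 genes, which turned to -0.0784 and -0.19 without probe sets ending in _x_at or _s_at, 6 of them higher and 1 lower with both, among them RBL1 (2.19-fold and 2.37-fold higher) and the cyclin gene CCND1 (1.86-fold and 3.33-fold higher). The lower member was CDKN2B (4.88-fold and 5.07-fold, chosen after its values were seen). Of 16 genes of the t(4;14) and MAF myeloma signature, 1 was lower, 1 higher and 14 neither, with medians of -0.25 (percentile 13.9) and 0.26 (percentile 94.7). The median with shMMSET#2 was 0.07 after scaling to the same median signal and 0.11 with the filter at the 75th percentile. CCND2 was 1.34-fold and 1.23-fold higher and ITGB7 1.21-fold and 1.85-fold higher. The lower member was ARHGAP25 (1.59-fold and 2.15-fold, chosen after its values were seen). SEPTIN9 was 1.92-fold and 1.85-fold higher and WDFY2 1.27-fold and 1.16-fold higher, and the probe sets of both genes disagreed in sign.

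Of 40 tested histone and lysine methylation enzymes, 4 were lower with both hairpins, 1 was higher and 35 were neither, with medians of -0.05 (percentile 27.4) and -0.23 (percentile 1.21), which scaling to the same median signal turned to 0.27 and 0.15. DNMT3B, a DNA methyltransferase gene, was 2.64-fold and 1.91-fold lower, and the demethylase genes KDM6B (1.86-fold and 1.82-fold) and KDM3A (1.65-fold and 1.69-fold) were lower, as was EZH1 (1.57-fold and 1.95-fold). The higher member was KMT5A (1.91-fold with shMMSET#2, chosen after its values were seen). Of 24 cholesterol synthesis genes, 1 was lower and 1 higher with both, with medians of 0.00 and -0.15 (percentiles 42.0 and 7.49), which scaling to the same median signal turned to 0.32 and 0.23. SREBF2, which encodes a regulator of the pathway, was 1.59-fold and 2.21-fold lower, MSMO1 1.36-fold and 2.46-fold, SQLE 1.40-fold and 1.91-fold, and STARD4 1.19-fold and 1.57-fold. The higher member was SREBF1 (2.16-fold and 2.56-fold, chosen after its values were seen). Of 30 adhesion and migration genes, 5 were lower and 5 higher with both, with medians of -0.14 and 0.00 (percentiles 14.0 and 51.1), the former 0.18 after scaling to the same median signal, and CDH1, the gene of E-cadherin, was 11.9-fold and 1.75-fold lower. SNAI2 was 2.31-fold and 1.87-fold lower and ITGAE 1.74-fold and 2.10-fold lower. The other lower members were ICAM1 and ITGA4 (1.53-fold and 1.65-fold). The higher members were CCR10 (3.51-fold and 5.26-fold), ITGAL (2.42-fold and 2.28-fold), S1PR1 (1.80-fold and 2.02-fold), ITGA6 (1.83-fold and 1.53-fold) and NCAM1. ITGA4 and these 5 were chosen after their values were seen. Of 10 replication-dependent histone genes, 1 was lower with both and none was higher with both, with medians of -0.02 and -0.20 (percentiles 41.8 and 14.0), which scaling to the same median signal turned to 0.30 and 0.18. H2AC6 was 1.52-fold and 2.42-fold lower, H2BC21 1.32-fold and 1.89-fold, H2AC8 1.25-fold and 1.67-fold, and H2BC5 1.03-fold and 1.15-fold. Of 10 tested T and NK cell markers, 3 were lower with both, with medians of -0.76 and -0.39 (percentiles 7.51 and 26.9). CD3D was at least 2.22-fold and KLRD1 at least 2.62-fold lower with each hairpin, CD7 at least 2.26-fold and 1.65-fold lower, and PRF1 2.14-fold and 1.49-fold lower. CD3D, KLRD1 and CD7 read 91.3, 108 and 93.1 on the shLuc array, near its median of 77.4, and below the median on each hairpin array. They were tested through the shLuc array alone, so the filter itself favours a lower value. Other probe sets of KLRD1 and CD7 were under the median on every array. Of 4 myeloid markers, none was lower or higher with both, with medians of 0.13 and -0.16 (percentiles 80.6 and 50.4), and ITGAM was 1.11-fold and 1.25-fold lower. Of 11 fibroblast and epithelial markers, 2 were lower with both, with medians of -0.42 and 0.10 (percentiles 11.1 and 77.6), the latter -0.74 with the filter at the 75th percentile, and FN1 was 2.60-fold and 3.06-fold lower. VIM was 1.34-fold and 1.59-fold lower, and DCN 1.35-fold and at least 2.08-fold lower.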
